A study of Mus musculus with 24 samples.

How the data were processed

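Gene expression was measured by bulk RNA sequencing of the subdissected entorhinal cortex of adult mice, 24 libraries in 4 groups of 6: vehicle, and 1, 2 and 3 days after activation of the GlyCl channel. Per the labels, RNA was extracted with a column kit and libraries were made and sequenced by a commercial provider. The deposited file is a single table of whole-number read counts per gene, not normalized, with 24 library columns, all of them used. It held 55417 genes, of which 55416 carried an Ensembl identifier and the remaining entry was the transgene marker EYFP. Per the submitters' processing notes, the tools named were fastp 0.23.1, STAR 2.7.9a and DESeq2 1.32.0, with the mm39 genome build; their roles and settings are not given in the sources used here. The program that counted reads, the annotation release and the use of strand are also not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and values of near-identical genes (C4b, Ifit3, Ccl3, Ccl4, Ccl12 and the haemoglobin genes) are uncertain to the extent that reads were split between copies.

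Gene symbols came from a table of Ensembl identifiers and symbols, in which 52083 identifiers were found. The reference annotation at hand was of another mouse build than mm39, so no coordinates are given. Groups were taken from the treatment label of each library, and each file column was matched to its library by name. Each library has its own animal number and sex in the labels, but the labels do not state in so many words that each came from a separate animal; if any did not, p-values would measure only the spread between these libraries. The time at which vehicle tissue was collected is not given in the labels. Vehicle held 4 females and 2 males, and each day held 3 of each. Xist and Ddx3y were used to check the sex labels. Library pairs within a group were compared by chi-square over genes to look for a library present more than once; the ratio of chi-square to degrees of freedom was 3.95 to 13.8 over 60 pairs, so none agreed within sampling noise.

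Counts were tested with edgeR 4.0.16 (quasi-likelihood test, two-sided) in R 4.3.3. Factors were trimmed mean of M values, genes were kept by the filterByExpr function (minimum count 10, minimum total 15), and the model held group and sex over all 24 libraries, which shared an estimate of the spread. The filter kept 16767 genes, 43 of them without a symbol. The biological coefficient of variation was 8.51%. Adjusted p-values are Benjamini-Hochberg values over all genes tested within a comparison, and a gene was called changed at an adjusted p under 0.05. Unless another tool is named, adjusted p-values of genes come from this edgeR test and log2 fold changes carry the standard error (SE) of the fit, with n = 6 per group. Each day was compared with vehicle, the days were compared with each other, the 3 days were tested jointly, and a group by sex interaction was tested.

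Before the data were examined, 36 gene lists with 548 genes were fixed. Of these genes, 511 were measured and 4 had no match in the table of symbols. The lists were tested with camera in limma 3.58.1 on voom log2 CPM (counts scaled to the library total) with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. A list score was the mean of its members' log2 CPM (prior count 2), each centred over all libraries, and was compared between a day and vehicle with a two-sided exact permutation test. The smallest p that 6 against 6 libraries can give is 0.00216, and score p-values were adjusted over all lists and days. The named genes followed a rule fixed at the same time. It took up to 8 rises and 8 falls of the largest size per day among called genes with a symbol and a mean log2 CPM of at least 1, the leading members of each list, and Glra1, Klk8, Reln, Calb1, Fos, Arc, Bdnf, Atf3, Gfap and Aif1 in any case; members counted in a sentence on a list are also named.

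The edgeR and camera steps were tested on simulated counts of 16596 genes with known changes at day 1 and day 3 and none at day 2. For day 1, 40% of 1.2-fold, 84% of 1.5-fold, 84% of 2-fold and 98% of 4-fold changes were recovered, and 3.77% of 159 calls were false. For day 3 the shares were 42%, 78%, 82% and 98%, and 5.92% of 169 calls were false. At day 2, where nothing had been changed, 1 gene and 1 of 35 lists were called. Simulated genes varied independently of each other, without differences in choroid plexus or animal number between libraries. These rates therefore need not hold for the real libraries, least of all for the list tests. Total counts per library ranged from 16.6 to 23.7 M reads, which set the precision of low genes.

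Alternatives fixed in advance were other normalization factors, other filters on low counts, DESeq2 1.42.0 and limma voom as tools, a model without sex, only the groups compared, the first digits of the animal number as a factor, a surrogate variable from sva 3.50.0, stricter thresholds, each sex alone, and leaving out each library in turn. A choroid plexus score as covariate and a fit without 8 libraries rich in choroid plexus transcripts were added after seeing the data. Log2 fold changes shared between days were set beside values from simulated unchanged groups and from vehicle libraries split 3 and 3, because all days share the vehicle libraries. The list of infiltrating leukocyte markers had 1 measured member of 12 and was left out of the list tests, which covered the other 35 lists. A few genes, 1 of them called lower at day 1, are counted but not reported here by name.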

Results

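RNA was sequenced from the dissected entorhinal cortex of adult mice, 2 to 4 months old, that carried the Nop-tTA driver and a tetracycline-responsive GlyCl-YFP transgene. GlyCl is an engineered chloride channel built on the glycine receptor, which silences the neurons that carry it once it is activated. The series asks how adult entorhinal neurons fare when their activity is taken away. There were 6 vehicle libraries (4 females and 2 males) and 6 libraries each (3 females and 3 males) from 1, 2 and 3 days after channel activation. Total counts averaged 19.5 ± 2.06 M reads (SD, n = 6) in vehicle, 20.02 ± 2.30 M at day 1, 18.4 ± 1.13 M at day 2 and 19.5 ± 1.52 M at day 3. Depth did not differ detectably from vehicle on any day (exact permutation test, two-sided, n = 6 per group, p = 0.710, 0.359 and 0.961).

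The transgene marker EYFP was counted in all 24 libraries, at 50.9 CPM (read counts scaled to the library total) or more. Xist, the X-inactivation transcript, was at 426 CPM or more in the libraries labelled female and at most 2.14 CPM in those labelled male, and Ddx3y, on the Y chromosome, was at most 0.109 CPM and at least 47.6 CPM respectively. Transcripts of the choroid plexus, the tissue that secretes cerebrospinal fluid, were abundant in 8 of the 24 libraries. Ttr, the main choroid plexus transcript, stood at 562 to 1171 CPM in these (1 vehicle, 2 day 1, 2 day 2 and 3 day 3 libraries) and at 8.37 to 25.9 CPM in the other 16.

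The comparison of day 1 with vehicle asked what a single day of silencing does to the tissue. Egr3 (ENSMUSG00000033730.5), a transcription factor induced by neuronal activity, fell by 0.74 ± 0.12 on the log2 scale (SE, n = 6 per group; edgeR adjusted p = 0.00602). It went from 233 ± 48.2 CPM (SD) in vehicle to 141 ± 20.3 CPM at day 1, and the highest day 1 library (175 CPM) lay below the lowest vehicle library (191 CPM). Dio2, the enzyme that activates thyroid hormone, fell by 0.52 ± 0.09 and Ephb3, an ephrin receptor, by 0.41 ± 0.07 (adjusted p = 0.00866 and 0.00633). Smaller falls were measured for Grasp, a postsynaptic scaffold protein (fell by 0.36 ± 0.07), Tmem198 (fell by 0.28 ± 0.04), Kcnh3, a potassium channel (fell by 0.27 ± 0.05), and Synpo, an actin-associated protein of dendritic spines (fell by 0.26 ± 0.05). Rises were C4b, a complement component, by 0.45 ± 0.09 and Elk1, a transcription factor, by 0.27 ± 0.05 (adjusted p = 0.0350 and 0.0170). Several of these calls were fragile. C4b, Elk1 and Grasp each stayed called in 10 of 16 alternatives, Kcnh3, Synpo and Ephb3 in 12, Dio2 in 13 and Egr3 and Tmem198 in 14. Without the 8 libraries rich in Ttr, 5 of the 11 lost their calls, C4b, Elk1, Grasp and Ephb3 among them, and 10 genes were called lower. Over all alternatives the log2 fold change stayed at -0.45 to -0.39 for Ephb3 and -0.39 to -0.32 for Grasp. The range was wider for C4b (0.37 to 0.56) and Elk1 (0.16 to 0.44). Grasp also lost its call with upper-quartile factors. Leaving out 1 library ended the call of C4b (Day1 1, 2, 3, 4 and 6 and Vehicle 4, 5 and 6), Grasp (Day1 1, 3, 4 and 5 and Vehicle 2, 4 and 6) and Synpo (Day1 1, 3, 4 and 5 and Vehicle 4 and 6). The same held for Kcnh3 (Day1 1 and 5 and Vehicle 1, 4 and 6), Elk1 (Day1 1 and 4 and Vehicle 1, 4 and 6) and Dio2 (Vehicle 6).

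Across the 16767 genes tested, 11 were called at day 1, 2 higher and 9 lower, and 1215 had an unadjusted p under 0.05. Of 17 immediate early genes, which neurons switch on within minutes of firing, Egr3 fell and 16 did not pass; adjusted over the list alone, 2 were lower, Egr3 and Nr4a3 (log2 fold change -0.59 ± 0.16, adjusted p over all genes 0.213). Fos and Arc, members of the same list, stood at -0.18 ± 0.39 and -0.34 ± 0.42 and did not pass (adjusted p = 0.962 and 0.927). None of the 14 late activity-regulated genes passed over all genes (0 called by edgeR), and 8 were lower when adjusted over the list alone. These included Homer1, a postsynaptic scaffold (-0.46 ± 0.10), Nptx2, a synaptic pentraxin (-0.50 ± 0.12), and Bdnf, a neurotrophin (-0.22 ± 0.09), and 1 of the 14 had a log2 fold change above 0. By camera, both lists were lower (adjusted p = 0.000296 for immediate early and 1.23e-08 for late genes), but with an estimated correlation neither was (adjusted p = 0.868 and adjusted p = 0.246). The score of the late list differed by -0.21 at day 1 (exact permutation p = 0.0130, n = 6 per group, adjusted p = 0.10).

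Other lists called by camera at day 1 were lost with an estimated correlation. Interneuron markers were lower (adjusted p = 0.0105; adjusted p = 0.246 with an estimated correlation), with 0 of 13 members called and 3 lower when adjusted over the list alone: Gad1 and Slc32a1, of GABA synthesis and packaging, and the peptide gene Sst (-0.12 ± 0.04, -0.15 ± 0.05 and -0.15 ± 0.05). Excitatory synapse genes (adjusted p = 0.00764) and nuclear-encoded oxidative phosphorylation genes (adjusted p = 0.0421) were lower, and deep cortical neuron markers (adjusted p = 0.0140) were higher. With an estimated correlation these were adjusted p = 0.246, adjusted p = 0.931 and adjusted p = 0.355, and 0 of 20, 0 of 24 and 0 of 11 members were called by edgeR. Cytokines and chemokines were not called at day 1 (camera adjusted p = 0.247), and 1 of 12 members, Ccl3, was higher adjusted over the list alone. Their score differed by 0.24 (exact permutation p = 0.0108, n = 6 per group, adjusted p = 0.0899). The day 1 count was 75 with DESeq2, 31 with limma voom, 31 with the animal number as a factor, 159 without the filter on low counts, 2 in females, 0 in males and 0 against a 1.2-fold threshold. Leaving out Vehicle 6, Vehicle 4, Day1 1 or Day1 4 gave 4, 5, 5 and 6 genes, and leaving out Day1 2, Day2 3 or Vehicle 3 gave 19, 22 and 28.

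**Figure D1:**
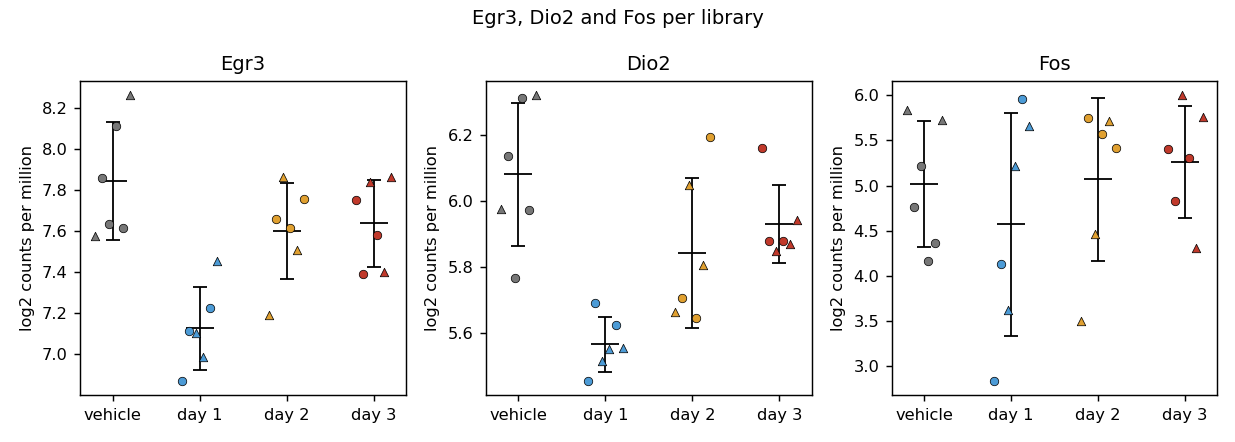
Log2 CPM of Egr3, Dio2 and Fos per library in the 4 groups (circles, females; triangles, males; bars, mean ± SD, n = 6). Egr3 averaged 233 CPM in vehicle and 141 CPM at day 1, and Fos overlapped between the groups.

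The comparison of day 2 with vehicle asked how the tissue had changed after a further day. Ccl3 (ENSMUSG00000000982.6) and Ccl4, chemokines of activated microglia, rose by 4.02 ± 0.53 and 3.51 ± 0.52 (log2 fold change ± SE, n = 6 per group; adjusted p = 0.000397 and 0.00114). Both were near the floor in vehicle: the 6 vehicle libraries held 6 Ccl3 reads and 5 Ccl4 reads in all, against 100 and 59 at day 2, so these folds are imprecise. Gfap, the intermediate filament of astrocytes, rose by 0.51 ± 0.08, from 187 ± 23.3 to 262 ± 34.8 CPM (SD), and C4b by 0.59 ± 0.09 (adjusted p = 0.00116 and 0.00114). Cd180, a Toll-like receptor relative, rose by 1.36 ± 0.22 and Slc15a3, a lysosomal peptide transporter, by 1.30 ± 0.22. Of the microglial lists, the chemokine Ccl6 rose by 1.05 ± 0.21 and Olfml3 by 0.48 ± 0.08. Ecel1 and Atf3, genes induced in injured neurons, rose by 0.88 ± 0.17 and 1.41 ± 0.29 (adjusted p = 0.0247 and 0.0499). Without the 8 libraries rich in Ttr, Ccl3 and Gfap stayed called, while Ccl4, C4b, Cd180, Slc15a3, Ccl6, Olfml3, Ecel1 and Atf3 lost their calls. Over all alternatives the log2 fold change stayed at 0.58 to 0.64 for C4b, 1.23 to 1.39 for Slc15a3 and 0.43 to 0.53 for Olfml3. The range was wider for Ccl4 (2.64 to 3.98), Cd180 (0.87 to 1.69), Ccl6 (0.77 to 1.22), Ecel1 (0.60 to 1.40) and Atf3 (0.83 to 1.82). With only the 2 groups compared, Gfap, C4b and Olfml3 stayed called and Cd180, Slc15a3, Ccl6, Ecel1 and Atf3 lost their calls. Ccl3 and Ccl4 gave no value in that fit.

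In total 11 genes were higher at day 2 and 0 lower by edgeR; limma voom and DESeq2 also called 0 lower, and 412 genes were lower at an unadjusted p under 0.05. Without the filter on low counts 51 were higher and 35 lower, and leaving out Day2 3 or Vehicle 3 gave 1 lower. Of 12 measured cytokine and chemokine genes, 2 rose over all genes, and 3 were higher adjusted over the list alone, Cxcl10 being added (2.48 ± 0.77, adjusted p over all genes 0.689). The list was higher by camera (adjusted p = 1.02e-06; adjusted p = 0.00677 with an estimated correlation), and its score was higher by 0.65, with 6 of 6 day 2 libraries above every vehicle library (exact permutation p = 0.00216, the smallest possible with n = 6 per group, adjusted p = 0.0390). The members had a median log2 fold change of 0.33 and a mean of 0.99, with 9 of 12 above 0. The score thus leans on Ccl3, Ccl4 and Cxcl10, which had few reads in vehicle. Genes of the integrated stress response, through which stressed cells curb protein synthesis, were higher as a list (adjusted p = 3.57e-05; adjusted p = 0.00677 with an estimated correlation). Their score did not pass (adjusted p = 0.0701). None of the 23 members passed over all genes (0 called by edgeR), and 4 were higher adjusted over the list alone: Sesn2 (0.32 ± 0.07), Ppp1r15a (0.27 ± 0.07), Trib3 (1.04 ± 0.31) and Shmt2 (0.18 ± 0.06). Interneuron markers were lower as a list (adjusted p = 0.000120; adjusted p = 0.0481 with an estimated correlation; adjusted p = 0.0899 for their score); 0 of 13 passed, and 3 were lower adjusted over the list alone, Gad1 (-0.11 ± 0.04), Slc32a1 (-0.15 ± 0.05) and Sst (-0.16 ± 0.05). The list of axon injury genes was higher by camera (adjusted p = 0.000652), with Atf3 and Ecel1 called among 15 members and adjusted over the list alone; adjusted p = 0.0904 with an estimated correlation.

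Glial lists were higher at day 2 by camera alone. They were homeostatic microglia (adjusted p = 3.67e-06; adjusted p = 0.169 with an estimated correlation), activated microglia (adjusted p = 0.000120; adjusted p = 0.169 with an estimated correlation) and complement (adjusted p = 2.79e-06; adjusted p = 0.131 with an estimated correlation). In each, 1 member was called over all genes (Olfml3 of 13, Ccl6 of 19 and C4b of 14), and 4, 6 and 3 were higher adjusted over the list alone. Red blood cell transcripts, which mark blood left in the tissue, were also higher by camera at day 2 (median log2 fold change 0.71, adjusted p = 6.02e-06; adjusted p = 0.131 with an estimated correlation); 0 of 5 were called by edgeR and 4 were higher adjusted over the list alone, among them Alas2 (1.02 ± 0.26) and Hbb-bt (0.92 ± 0.30). The day 2 count was 18 with DESeq2, 86 without the filter on low counts, 7 with a filter of 1 CPM, 3 with only the 2 groups compared, 0 in either sex alone, 4 against a 1.2-fold threshold and 2 without the 8 libraries rich in Ttr. Leaving out Day2 2 or Vehicle 5 gave 7 genes. The calls of Atf3 and Ccl6 each held in 5 of 16 alternatives. They held in 5 and 11 of the 24 fits that leave out a library. Ecel1 held in 10 alternatives and lost its call without Day2 2 or Vehicle 1, 5 or 6.

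**Figure D2:**
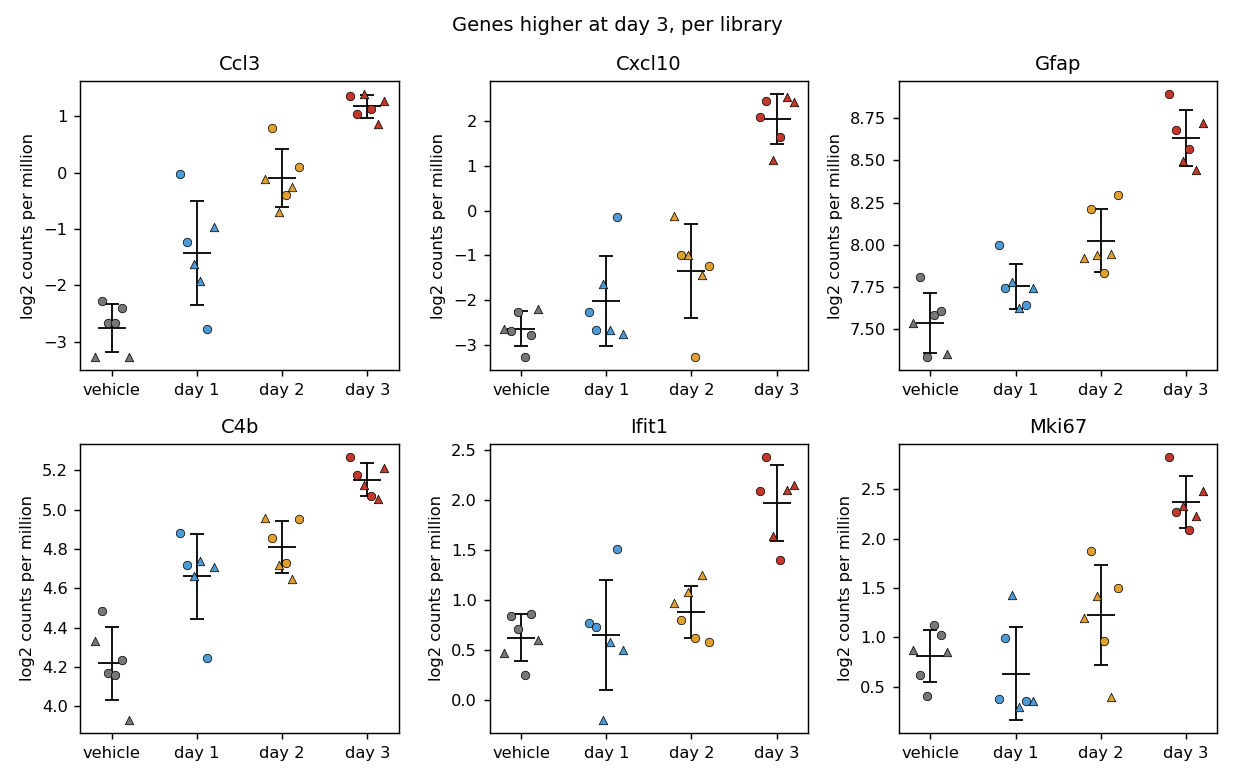
Log2 CPM of Ccl3, Cxcl10, Gfap, C4b, Ifit1 and Mki67 per library in the 4 groups (circles, females; triangles, males; bars, mean ± SD, n = 6). Gfap averaged 187, 217, 262 and 399 CPM in vehicle and at days 1, 2 and 3.

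The comparison of day 3 with vehicle gave the largest number of calls against vehicle. Gfap (ENSMUSG00000020932.15) rose by 1.12 ± 0.08 (log2 fold change ± SE, n = 6 per group; adjusted p = 1.77e-10), to 399 ± 46.6 CPM (SD), and the lowest day 3 library (348 CPM) lay above the highest vehicle library (224 CPM). Cxcl10, a chemokine induced by interferon, rose by 6.0 ± 0.56, Ccl3 by 5.32 ± 0.47 and Ccl4 by 4.82 ± 0.45 (adjusted p = 5.9e-08, 4.34e-08 and 5.9e-08), from 7, 6 and 5 reads over the vehicle libraries to 508, 255 and 156 at day 3. Mki67, a marker of dividing cells, rose by 1.62 ± 0.21, and Isg15, an interferon-induced ubiquitin-like protein, by 1.79 ± 0.24 (adjusted p = 2.42e-05 and 2.73e-05). The transgene went the other way. EYFP fell by 0.89 ± 0.11, from 113 ± 19.5 to 61.7 ± 9.82 CPM (adjusted p = 1.19e-05), and Glra1, the mouse gene of a glycine receptor subunit, fell by 0.83 ± 0.13, from 13.1 ± 2.62 to 7.57 ± 1.23 CPM (adjusted p = 0.000636). After group and sex were fitted, Glra1 and EYFP varied together over the 24 libraries (Pearson's r = 0.770, Spearman's rho = 0.783, permutation p = 3e-05 for each; r = 0.682 with the animal number also fitted).

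Of 103 genes called at day 3, 2 were lower, EYFP and Glra1, and the others were higher. With DESeq2, limma voom or the animal number as a factor, 4, 4 and 5 genes were lower, and 40 without the filter on low counts. At an unadjusted p under 0.05 there were 946 genes. Among 20 interferon response genes, 10 rose, 10 did not pass, and 17 were higher adjusted over the list alone. Examples were Ifit1 (1.44 ± 0.21), Ifit3 (1.23 ± 0.19), Oasl2 (1.43 ± 0.23) and Irf7, a master regulator of the response (0.93 ± 0.19). The list was higher (camera adjusted p = 4.26e-37; adjusted p = 6.76e-05 with an estimated correlation) and all 20 log2 fold changes were above 0. Of 21 proliferation genes, 4 rose (Mki67, Top2a at 1.73 ± 0.28, Bub1b at 1.64 ± 0.35 and the replication gene Mcm3 at 0.88 ± 0.15), 17 did not pass, and 16 were higher adjusted over the list alone (camera adjusted p = 2.52e-31; adjusted p = 3.73e-06 with an estimated correlation). Of 12 cytokines and chemokines, 4 rose, with Ccl12 (3.64 ± 0.42) as the remaining member, and 9 were higher adjusted over the list alone (camera adjusted p = 1.72e-23; adjusted p = 3.73e-06 with an estimated correlation).

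Microglial genes rose at day 3. Of 19 activated microglia genes, 9 rose and 13 were higher adjusted over the list alone, among them Clec7a, a pattern receptor (3.01 ± 0.58), Itgax, an integrin (1.96 ± 0.35), Trem2, a lipid-sensing receptor (0.48 ± 0.08), and its adaptor Tyrobp (0.69 ± 0.12). Their list was higher (camera adjusted p = 6.17e-34; adjusted p = 5e-05 with an estimated correlation), with a median log2 fold change of 0.34. Of 13 homeostatic microglia genes, 4 rose (among them Cx3cr1, Fcrls and Olfml3, by 0.26 ± 0.06, 0.70 ± 0.11 and 0.68 ± 0.08), and 7 were higher adjusted over the list alone (camera adjusted p = 1.56e-17; adjusted p = 0.00685 with an estimated correlation; median 0.20). The pan-microglial gene Aif1 was at 0.11 ± 0.10 and did not pass. Of 14 complement genes, 4 rose, namely C4b (0.93 ± 0.09), C1qb (0.41 ± 0.08), C1qc (0.50 ± 0.12) and Itgb2 (0.68 ± 0.14), and 7 were higher adjusted over the list alone (camera adjusted p = 2.65e-15; adjusted p = 0.00570 with an estimated correlation). Of 15 reactive astrocyte genes, Gfap and Aspg (0.71 ± 0.16) rose and 4 were higher adjusted over the list alone (camera adjusted p = 6.34e-10; adjusted p = 0.00215 with an estimated correlation). Leaving out 1 library ended the call of Aspg (Day3 1 and 6 and Vehicle 1, 3 and 4), Itgb2 (Day3 1 and Vehicle 6) and C1qb (Day3 1). By contrast the general astrocyte markers had 0 of 11 called by edgeR (camera adjusted p = 0.677), Aqp4 being at 0.12 ± 0.06. Choroid plexus markers had a median log2 fold change of 0.71 in the same comparison and were not called (camera adjusted p = 0.515).

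Among neuronal lists at day 3, interneuron markers were lower (median log2 fold change -0.08, camera adjusted p = 0.000248; adjusted p = 0.0243 with an estimated correlation), with 1 of 13 above 0 and 0 called by edgeR, over all genes or adjusted over the list alone. Superficial cortical and entorhinal markers were not called (median -0.02, camera adjusted p = 0.120); Reln, which marks entorhinal stellate cells, was at -0.02 ± 0.07, Calb1 at 0.05 ± 0.05 and Wfs1 at -0.16 ± 0.06. Klk8, also called neuropsin, was at -0.08 ± 0.20. Apoptosis machinery genes were not called at day 3 (camera adjusted p = 0.515, 0 of 20 called by edgeR, 0 adjusted over the list alone), nor were p53 targets (camera adjusted p = 0.520, 0 of 16 called, and 1 higher and 1 lower adjusted over the list alone). Of the axon injury list, Atf3 (1.53 ± 0.28) and Ecel1 (1.04 ± 0.17) rose and 13 members did not pass, the list itself not being called (camera adjusted p = 0.0961). Its score was higher by 0.18, with 6 of 6 day 3 libraries above every vehicle library (exact permutation p = 0.00216, n = 6 per group, adjusted p = 0.0390). The median log2 fold change of its members was 0.024, so the score mostly restates these 2 genes. Atf3 lost its day 3 call without the 8 libraries rich in Ttr, as did Itgb2 and the oxidative stress gene Hmox1. These genes also lost it in females alone and in males alone. The score tests at day 3 did not pass for interneuron markers (adjusted p = 0.222), complement (adjusted p = 0.0701), homeostatic microglia (adjusted p = 0.0584) or reactive astrocytes (adjusted p = 0.0584). The day 3 count was 217 without the filter on low counts, 65 at an adjusted p under 0.01 and 53 against a 1.2-fold threshold. It was 35 in females, 12 in males and 49 without the 8 libraries rich in Ttr, all 49 shared with the 103. With the animal number as a factor it was 96, of which 82 were shared with the 103.

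**Figure D3:**
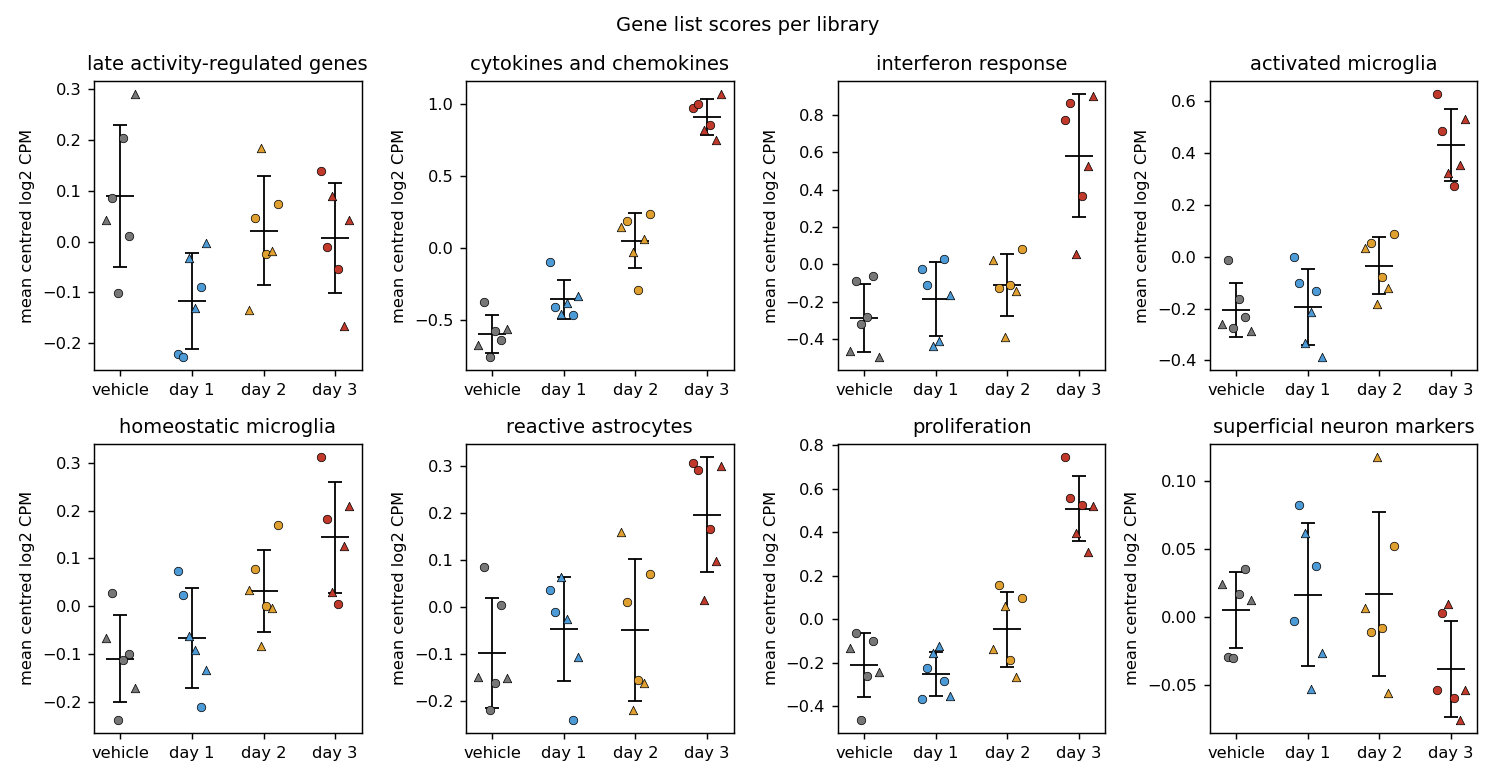
Score of 8 gene lists per library, the mean centred log2 CPM of the members, in the 4 groups (circles, females; triangles, males; bars, mean ± SD, n = 6). The cytokine and chemokine score was higher than in vehicle by 0.65 at day 2 and 1.51 at day 3.

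**Figure D4:**
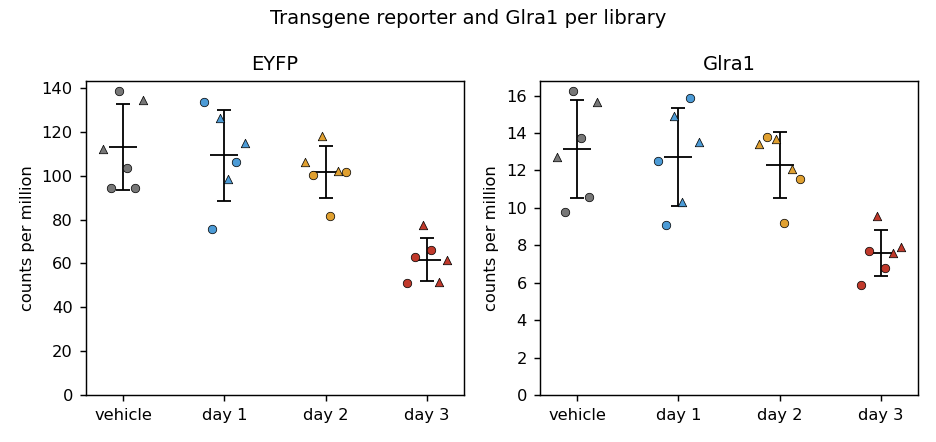
CPM of EYFP and Glra1 per library in the 4 groups (circles, females; triangles, males; bars, mean ± SD, n = 6). EYFP lay between 94.3 and 139 CPM in vehicle and between 50.9 and 77.4 CPM at day 3.

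The days were then compared directly, to ask when the changes took place. From day 1 to day 2, Ccl4 rose by 2.58 ± 0.45 and Mmp15, a membrane matrix metalloproteinase named after its value was seen, by 0.40 ± 0.07 (adjusted p = 0.0323 for each, SE, n = 6 per group). From day 2 to day 3, Cxcl10 rose by 3.51 ± 0.42, Gfap by 0.61 ± 0.08, Ifit3 by 1.08 ± 0.19 and Mki67 by 1.12 ± 0.21 (adjusted p = 5.48e-05, 6.67e-05, 0.00529 and 0.0116). EYFP fell by 0.72 ± 0.11 and Glra1 by 0.71 ± 0.13 over the same interval (adjusted p = 0.00236 and 0.0182). From day 1 to day 3, Egr3 rose by 0.51 ± 0.12, Dio2 by 0.37 ± 0.09 and Ephb3 by 0.39 ± 0.07, while Elk1 fell by 0.23 ± 0.05 (adjusted p = 0.0291, 0.0474, 0.00224 and 0.0232). At day 3 these 4 genes did not pass against vehicle (Egr3 at -0.23 ± 0.12, Dio2 at -0.16 ± 0.09, Ephb3 at -0.03 ± 0.07 and Elk1 at 0.05 ± 0.05).

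Between days 1 and 2, 2 genes were called (both higher), between days 2 and 3, 22 (20 higher and 2 lower), and between days 1 and 3, 109 (8 lower and the others higher); the joint test of the 3 days called 108. With the animal number as a factor the first 3 counts were 0, 6 and 53, and without the 8 libraries rich in Ttr they were 1, 6 and 47. Leaving out Day3 1, Day3 2 or Day3 6 gave 10, 12 and 13 genes between days 2 and 3, and leaving out Day3 6, Day3 1, Day1 5 or Day1 6 gave 44, 53, 62 and 67 between days 1 and 3; the joint count was 68 without Day3 1 or Day3 6. Between days 1 and 2, leaving out any of 14 libraries gave 0 or 1 genes.

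**Figure D5:**
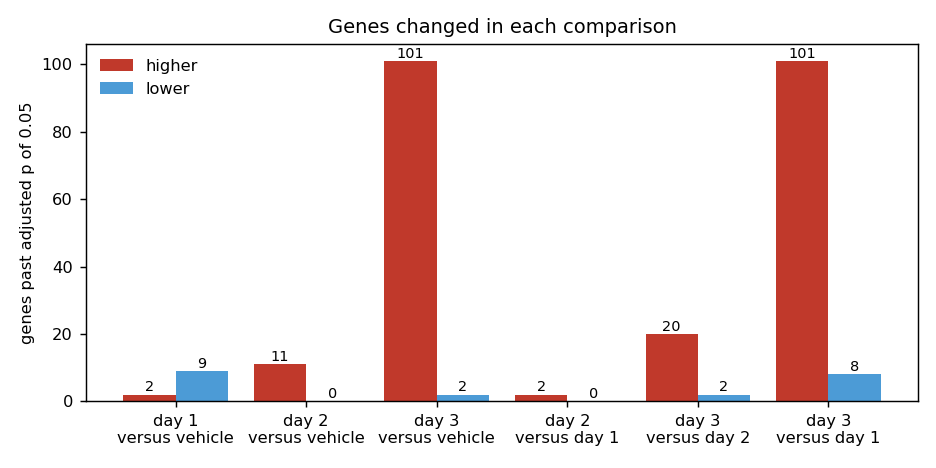
Number of genes called higher and lower by edgeR at an adjusted p under 0.05 in each comparison. Day 3 against vehicle had 103 genes, 2 of them lower, and day 1 against vehicle had 2 higher and 9 lower.

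Changes from vehicle were compared across days over 16767 genes, which are not independent replicates. For days 2 and 3, Pearson's r of the log2 fold changes was 0.605 and the covariance 0.0231. In 20 simulations of unchanged groups against the same vehicle libraries, r averaged 0.516 and the covariance 0.0150, which leaves a covariance difference of 0.00808. With the vehicle libraries split 3 and 3 between the comparisons, the median r over 20 splits was 0.149 (0.0922 to 0.209) and the median covariance 0.00869. Days 2 and 3 shared 11 higher calls, and 0 to 6 with split vehicle libraries. Independent lists would share 0.0663, but these lists rest on the same vehicle libraries. No simulation had calls in the same direction on both days, so its overlap of 0 was fixed and sets no benchmark. For days 1 and 2, r was 0.563 (simulated mean 0.508), the covariance difference 0.00284 and the median split r 0.0476. For days 1 and 3 these were 0.477 (0.512), 0.00320 and 0.0584. C4b was the gene called higher on all 3 days. Its day 1 call was lost in 6 of 16 alternatives and when any 1 of 8 libraries was left out.

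Whether the change after activation differed between females and males was tested with an interaction of group and sex. By edgeR 0 genes passed, with 585 at an unadjusted p under 0.05, and limma voom and DESeq2 also called 0. Vehicle held only 2 males, and without the filter on low counts 175 genes passed.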

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

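The tests of a larger microglial share, of less superficial tissue and of transgene reads at Glra1 were chosen only after the results were seen. The fit with the choroid plexus score was also added after the data were seen, with its prediction written before its result, and the check of other immediate early genes was added to the test of stimulation after its result.

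Single libraries stood apart from the other 5 of their group by Dixon's ratio in 10 of 180 gene groups, 5 of 144 list-score groups and 2 of 4 groups of totals, where chance gives about 1 in 20. In log2 CPM, C4b was 4.25 in Day1 5 (others 4.66 to 4.88), Calb1 7.03 in Vehicle 1 (7.26 to 7.38), Ccl4 -0.25 in Day3 5 (0.51 to 0.73), Ccl6 2.27 in Day3 6 (1.68 to 1.84) and Cd180 1.08 in Day2 5 (1.53 to 1.80). Likewise Dio2 was 6.16 in Day3 1 (5.85 to 5.94), Ecel1 4.47 in Day3 4 (4.82 to 4.94), Isg15 0.63 in Day3 3 (1.78 to 2.06), Itgb2 2.55 in Day1 1 (1.85 to 2.09) and Olfml3 4.37 in Day1 1 (4.00 to 4.06). Among list scores, apoptosis machinery was -0.059 in Day2 3 (0.01 to 0.04), cytokines and chemokines -0.10 in Day1 1 (-0.47 to -0.34), deep cortical markers -0.094 in Day1 2 (0.06 to 0.14), choroid plexus markers 2.11 in Vehicle 5 (-1.23 to -0.54) and mitochondrially encoded transcripts 0.38 in Day2 6 (-0.15 to -0.08). Total counts were 23.4 M reads in Vehicle 5 (others 17.8 to 19.7) and 16.6 M in Day3 3 (19.3 to 20.8).

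For 33 named genes the change from vehicle differed between days by the direct edgeR test (log2 difference, n = 6 per group). From day 1 to day 3, chemokine and interferon genes differed by 4.19 (Cxcl10), 3.90 (Ccl4), 2.7 (Ccl3), 1.29 (Ccl6), 1.34 (Isg15), 1.31 (Ifit1) and 1.09 (Ifit3), and Oasl2 differed by 1.12 from day 2 to day 3. Proliferation genes differed from day 1 to day 3 by 2.12 (Top2a), 1.76 (Mki67) and 0.66 (Mcm3). Microglial and complement genes differed by 1.09 (Cd180), 1.05 (Capg), 0.92 (Slc15a3), 0.66 (Itgb2), 0.56 (Trem2), 0.50 (Olfml3), 0.48 (Fcrls), 0.48 (C4b), 0.41 (Ctsz) and 0.35 (C1qb). Gfap differed by 0.88, Ecel1 by 0.76 and Hmox1 by 0.58. Genes lower at day 1 differed by 0.51 (Egr3), 0.39 (Ephb3), 0.37 (Dio2), 0.30 (Grasp), 0.21 (Kcnh3) and 0.20 (Synpo), Elk1 by -0.23, EYFP by -0.83 and Glra1 by -0.76.

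The genes that rose at day 3 were led by glial and inflammatory genes. Their median log2 fold change was 0.88 without the choroid plexus score in the model and 0.88 with it (100.3% of the first), and 93 stayed called. The median absolute log2 fold change of the choroid plexus members went from 0.84 to 0.15, but the score is made from these members. The genes that rose had been called in these same libraries, a choice that favours genes whose spread does not follow the score. The score test therefore cannot decide whether carry-over of choroid plexus was a source. Without the 8 libraries rich in Ttr, 47 genes were still called higher at day 3, all among the 103, so their rise did not rest on those libraries. A larger share of microglia alone would raise genes made only by microglia alike. The activated score rose by 0.38 ± 0.03 (SE) more than the homeostatic score (0.64 against 0.25, exact permutation p = 0.00216, n = 6 per group). The median log2 fold changes of the lists lay closer together, at 0.34 and 0.20. Whether all listed genes are made only by microglia was not tested. A change of state of glial cells after silencing is thus a hypothesis that these values allow. Such a change together with a larger share of microglia is another, as all 13 homeostatic genes had a log2 fold change above 0. Effects of the activating treatment itself and of the day on which vehicle tissue was collected were not tested here and stay open.

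EYFP and Glra1 fell together at day 3. A superficial marker score of -0.45 or lower was set to count for less superficial entorhinal tissue, and a value above -0.22 against it. These limits were fractions of the EYFP fall, chosen after the results were seen. The score differed by -0.043 ± 0.018 (SE, exact permutation p = 0.0541, n = 6 per group). How far a loss of such tissue would move this score was not measured, so the test cannot decide. The 50 genes that follow EYFP between libraries were predicted to differ by a median of -0.28 if less transgene-carrying tissue was sampled. They differed by -0.01, which is 3.32% of that, with 27 of 50 below 0 and 0 called by edgeR. These genes and their slopes on EYFP were picked from the same libraries, a choice that inflates the slopes and so the predicted fall. Whether the genes mark tissue that carries the transgene was not tested, so this comparison cannot decide either. For Glra1, reads of the transgene counted at the mouse gene are a candidate source: its residual correlation with EYFP was 0.770 (0.778 without the 2 farthest libraries, 0.682 with the animal number as a factor), rank 6 among 16766 genes (5 other genes followed EYFP more closely, the highest at 0.854), and the log2 difference between them was 3.10 ± 0.11 (SD) in vehicle and 3.01 ± 0.17 at day 3 (exact permutation p = 0.303, n = 6 per group). Whether fewer cells carried the transgene, or each carried less of its transcript, stays open.

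Egr3, Dio2 and other genes fell at day 1. Different stimulation of the animals before tissue collection would act through rapid genes such as Fos and Arc, whose mean differed by -0.48 ± 0.59 (SE; exact permutation p = 0.429, n = 6 per group). With both in the model, the median log2 fold change of 14 other immediate early genes not called lower went from -0.18 to -0.00029, while that of the 9 genes was -0.35 against -0.36 without them (97.9%), and 7 stayed called. The 9 genes had been called in these same libraries, a choice that favours genes whose spread does not follow Fos and Arc. The test therefore cannot decide whether stimulation acting through Fos and Arc was a source of these falls. The same limit holds for lower neuronal activity as far as it acts through Fos and Arc. Sources that do not act through them were not tested and stay open.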

How the results depend on the processing

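The fits with a choroid plexus score and without the 8 libraries rich in Ttr were chosen after seeing the data; the other alternatives were fixed before. Over 49 called pairs of named gene and comparison and their 1956 alternatives, 0 log2 fold changes reversed. Genes named only as counted list members were not among these pairs. They include Clec7a, Itgax, Tyrobp, Cx3cr1, C1qc, Irf7, Bub1b and Ccl12 at day 3. Gfap, C4b, Ccl3, Ccl4, Cxcl10, Slc15a3, Ecel1 and EYFP stayed called at day 3 in every alternative that gave a value, 16 for each but Ccl4, which had 15. Glra1 lost its day 3 call in females alone and in males alone. Counts for day 1, day 2 and day 3 against vehicle, day 2 against day 1, day 3 against day 2, day 3 against day 1 and the joint test were 11, 11, 103, 2, 22, 109 and 108. Without the filter on low counts they were 159, 86, 217, 58, 79, 295 and 433, and the interaction gave 175, with more genes of few counts tested. At an adjusted p under 0.01 they were 5, 7, 65, 0, 9, 41 and 63, and against a 1.2-fold threshold the first 6 were 0, 4, 53, 0, 6 and 29, as stricter thresholds require. With fewer libraries, they were 2, 0, 35, 0, 0, 10 and 25 in females and 0, 0, 12, 0, 3, 13 and 13 in males; without the libraries rich in Ttr, day 2, day 3 and the following 4 gave 2, 49, 1, 6, 47 and 59; with only the groups compared, day 2 gave 3 and day 2 against day 1 gave 0. With the animal number as a factor, day 1 gave 31 (all 11 shared), day 2 against day 1 gave 0, day 3 against day 2 gave 6 and day 3 against day 1 gave 53. DESeq2 gave 75 at day 1, 18 at day 2, 36 for day 3 against day 2 and 208 jointly, limma voom gave 31 at day 1, and a 1 CPM filter gave 7 at day 2 and 1 for day 2 against day 1; for these and the animal number the cause was not tested. Other normalization factors, a model without sex, a surrogate variable and the choroid plexus score left each of these counts within 1.5 times. Lists called fell from 6, 16 and 13 to 0, 3 and 8 with an estimated correlation and with fry, which allow for correlated members.

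Leaving out each library in turn gave 4 to 28 genes at day 1, 7 to 12 at day 2, 72 to 110 at day 3, 0 to 2 for day 2 against day 1, 10 to 28 for day 3 against day 2, 44 to 117 for day 3 against day 1, 68 to 132 jointly and 0 to 0 for the interaction, and 4 to 13, 13 to 19 and 11 to 18 lists at days 1, 2 and 3. The highest list count of day 1 came without Day1 5. No paired analysis was possible because each library has an animal number of its own; the first digits of that number, which libraries share across groups, were the block in the fits with the animal number as a factor. Depth limits Ccl3, Ccl4 and Cxcl10, with 6, 5 and 7 reads over the 6 vehicle libraries.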

Other observations

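The tests in this part were written down before their results were seen. Other gene lists were called by camera at day 2 and lost with an estimated correlation. Proliferation genes were higher (median log2 fold change 0.18, adjusted p = 0.000942; adjusted p = 0.131 with an estimated correlation), as were interferon genes (0.16, adjusted p = 0.0122; adjusted p = 0.448 with an estimated correlation) and cholesterol synthesis genes (0.05, adjusted p = 0.000117; adjusted p = 0.288 with an estimated correlation). Oligodendrocyte markers were lower (-0.13, adjusted p = 0.000210; adjusted p = 0.448 with an estimated correlation), with 0 of 12 above 0, and so were astrocyte markers (-0.05, adjusted p = 0.00961), mitochondrially encoded transcripts (-0.08, adjusted p = 0.00411), glucocorticoid targets (-0.05, adjusted p = 0.0351) and striatal and amygdalar markers (-0.13, adjusted p = 0.0213). With an estimated correlation these last 4 had adjusted p = 0.448, adjusted p = 0.448, adjusted p = 0.448 and adjusted p = 0.547. None of these lists had a member called over all genes at day 2 (0 by edgeR).

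At day 3, late activity-regulated genes (median -0.09, adjusted p = 0.00889), voltage-gated ion channels (-0.05, adjusted p = 0.00265), glucocorticoid targets (-0.14, adjusted p = 0.00265) and circadian clock genes (-0.06, adjusted p = 0.0318) were lower by camera, and red blood cell transcripts higher (0.36, adjusted p = 0.0137). With an estimated correlation they had adjusted p = 0.361, adjusted p = 0.345, adjusted p = 0.273, adjusted p = 0.381 and adjusted p = 0.361. Stress lists were not called at day 3: camera gave adjusted p = 0.0634 for the integrated stress response, 0.0558 for the unfolded protein response, 0.330 for heat shock genes and 0.135 for oxidative stress genes, of which Hmox1, which breaks down haem, rose (0.62 ± 0.12, adjusted p = 0.00381). Nor were immediate early genes (0.947), excitatory synapse (0.0595), inhibitory synapse (0.197), deep cortical (0.109), dentate granule cell (0.102), striatal and amygdalar (0.255), oligodendrocyte (0.520), oligodendrocyte precursor (0.947), endothelial and mural (0.102), mitochondrially encoded (0.138), nuclear-encoded oxidative phosphorylation (0.800) or cholesterol synthesis genes (0.823). Itgal, the measured member of the infiltrating leukocyte list, was at -0.13 ± 0.28.

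Each count was set beside 100 groupings of its libraries, the real one included, drawn without regard to animal number. For day 3 against day 1 (95 genes, highest other 39) and the joint test (108, highest other 23), only the real grouping gave such a count. These values argue against chance of this kind for both. Few groupings were as large for day 3 (2 of 100, with 86 genes, highest other 86), day 1 (3, with 14, highest other 76) and day 2 against vehicle (3, with 3, highest other 17). The same held for day 3 against day 2 (3, with 19, highest other 31). Each of these lay under the limit for chance set beforehand, a share of 0.05 of the groupings. In each, another grouping gave as many genes or more, so chance is not excluded by that stricter measure. Counts for pairs of groups came from fits of the compared libraries alone, so day 2 had 3 genes here and not 11. Chance is not excluded either for day 2 against day 1 (100 as large, 0 genes, highest other 54) or the interaction (100, 0, highest other 1). Nor is it for the list counts of day 1 (69, with 6, highest other 19), day 2 (9, with 15, highest other 20) and day 3 (21, with 16, highest other 19) at the preset correlation. The grouping with 86 genes at day 3 shared 0 genes with the real calls and divided 0 classes of animal number. Its sides held 1 and 3 libraries rich in Ttr. A structure of the libraries that follows the animal numbers is thus a candidate, not told apart from others. With that number as a factor, day 3 against vehicle gave 96 genes where it had given 103, with 82 shared. Day 3 against day 1 gave 53 where it had given 109, and day 3 against day 2 gave 6 where it had given 22. Whether chance within the classes of animal number would give as many was not tested. The grouping with 54 genes for day 2 against day 1 also divided 0 classes, and there the factor gave 0 genes. At day 1 the grouping with 76 genes shared 0 with the real calls and divided 3 classes, a structure for which no explanation was tested.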
